A study of Homo sapiens with 24 samples.

How the data were processed

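RNA from MCF10A cells, an established non-tumorigenic human mammary epithelial cell line, was measured on Illumina BeadChip expression arrays, on which each probe is read as the mean brightness of the beads that carry it. Per the labels' protocols, 3 stable lines were used. One carried an empty control vector (vector cells), and the others expressed the CYT1 or the CYT2 isoform of the receptor tyrosine kinase ERBB4. Each line was starved of serum for 48 h and then incubated for 2 h with or without the ERBB4 ligand neuregulin 1 (NRG1). RNA was extracted with the RNeasy Plus Mini Kit and turned into biotinylated cRNA with the Illumina TotalPrep kit, per the labels' protocols. The series title describes the introduced receptors as full-length JM-a ERBB4, while the sample characteristics add the letters ICD to the isoform name, and the lines are called CYT1 and CYT2 cells here. The 6 groups held 2 biological samples each, and each biological sample was measured on 2 technical replicate arrays, 24 arrays in all. The labels call the samples biological replicates without saying whether they came from separate cultures, so the p-values measure the spread between these samples.

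The deposited scanner table gives, per the file headers, an intensity (the mean bead signal, never below 0) and a detection p-value for each of 47323 probes on each array. The scanner and its software are not given in the sources used here. The authors' value table holds log2 values, deposited for the same arrays. Set against the scanner table, each of its columns equalled the log2 of that array's signal to within 5e-09, so it carries no background correction, normalization or centring, and its columns had medians of 6.83 to 6.98. Column names in the scanner table were matched to samples by line, biological and technical replicate and ligand, and that identity bore the match out for each array. Probes were named through the platform annotation. In it, 30113 probes had 1 gene symbol, 8 had several and 17202 were not listed, and 30074 symbols were matched to current ones through the gene identifier. Probes with several symbols or none were not named. Files named no chips, slides or scan dates, so no chip could be tested as a batch.

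Between 18745 and 20370 probes per array (39.6% to 43% of the total) had a detection p under 0.05, and the median signal ran from 114 to 126.3 units. The number of arrays limits the precision of every value. Intensities were background-corrected and quantile normalized with neqc in limma 3.58.1 (R 4.3.3), with an offset of 16 and the negative controls inferred from the detection p-values. A probe was kept if its detection p was under 0.05 on at least 4 of the 24 arrays, which left 23019 probes, 16620 of them named. For each gene the probe with the highest mean log2 intensity over all arrays was used, giving 12357 genes. Technical replicate arrays were averaged before the fit, so that n = 2 per group. Their root mean square log2 difference over genes was 0.179 to 0.208 within a sample, against 0.158 to 0.255 between averaged biological samples of a group.

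All 12 biological samples entered 1 linear model of group means (lmFit and eBayes in limma, 6 residual and 6.31 prior degrees of freedom), and p-values were adjusted with Benjamini-Hochberg over all genes in each comparison. The threshold was an adjusted p under 0.05. The 10 comparisons were fixed before the data were examined, together with their tests, the alternatives and the gene lists. They were the effect of NRG1 in each line, the 3 differences of those effects between lines, each ERBB4 line against vector cells without ligand, and CYT1 against CYT2 cells with and without ligand. CYT1 and CYT2 cells with NRG1 against vector cells with NRG1 were added after seeing the data. Where every array of a group lay below detection, a fold is given as "at least N-fold", from the bright group's mean over the higher of the lowest detected signal and the dim probe's own value.

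The rule for named genes was as follows. In the 5 main comparisons (NRG1 in each line, and each ERBB4 line against vector without ligand), the 8 largest rises and the 8 largest falls were taken among genes past the threshold whose 2 groups did not overlap. Up to 4 members of each gene list past the threshold were added. In the other comparisons the 5 largest in each direction were taken by the same rule. Where fewer than 3 genes qualified, the 3 with the smallest p are given as values. EGFR, ERBB2, ERBB3 and ERBB4 were always looked up. Genes named outside this rule were chosen after their values were seen, and the text says so there.

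The 21 gene lists, with 385 entries in all, covered signalling targets (immediate-early genes, ERK pathway feedback genes, ERBB receptors and ligands, YAP and TEAD target genes, STAT5 target and milk genes, inflammatory and NF-kB target genes, interferon-stimulated genes), metabolism (cholesterol synthesis and uptake, fatty acid synthesis), growth and stress (DNA replication genes, mitosis genes, hypoxia genes, amino acid and ER stress response genes, p53 target genes), epithelial state (epithelial adhesion genes, mesenchymal genes, basal keratinocyte-type genes, keratinocyte differentiation genes, luminal mammary genes) and other cell types (fibroblast markers, immune and endothelial markers). Lists with at least 5 measured genes were tested with camera (limma) at a preset correlation of 0.01, adjusted over the lists within a comparison. Camera with an estimated correlation and fry, which asks whether a list's genes move on balance one way, were alternatives, fry being added after seeing the data. At the preset correlation 63 list results over the 10 comparisons passed. With an estimated correlation 0 passed, and fry kept 14 of the 63.

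The procedure was tested on simulated data drawn from the real means and spreads, with 50 genes changed at each of 4 sizes. For the effect of NRG1 in CYT2 cells it recovered 40%, 96%, 94% and 100% of genes changed by 0.5, 1, 1.5 and 2 on the log2 scale, with 10 calls among 12157 unchanged genes. For the difference of NRG1 effects between CYT2 and vector cells the shares were 12%, 70%, 100% and 100%, with 7 calls among unchanged genes. Alternatives covered the background correction, the authors' value table, the filter on dim probes (none, or a detection p under 0.01 on all arrays of a group), each set of technical arrays alone, all 24 arrays with the biological sample as a random block, the replicate number as a block, eBayes with trend and robust, fits on only the groups compared, all probes, a minimum fold of 1.5 and leaving out each biological sample in turn. Leaving out the second array of CYT1 sample 2 without ligand, which stood apart from its technical twin, was added after seeing the data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.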

Results

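The series asked how the CYT1 and CYT2 isoforms of ERBB4, which differ in their cytoplasmic tail, change gene expression in MCF10A cells before and after their ligand NRG1. CYT1 carries a stretch, absent from CYT2, that can bind phosphatidylinositol 3-kinase. Vector, CYT1 and CYT2 cells were each measured without ligand and after 2 h of NRG1, with n = 2 biological samples in each of the 6 groups and 2 arrays per sample. Over all 24 arrays the first principal component held 17.7% of the variance and the second 15.1%. CYT2 cells without ligand lay at -17.49 to -12.54 on the first, and NRG1 moved them to 0.42 to 4.38. Sample 1 of CYT1 cells with NRG1 stood apart at 18.24 and 18.44, against 0.64 on both arrays of sample 2. Values below are log2 changes with the standard error of the fit, and a value of 1 is a doubling.

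**Figure D1:**
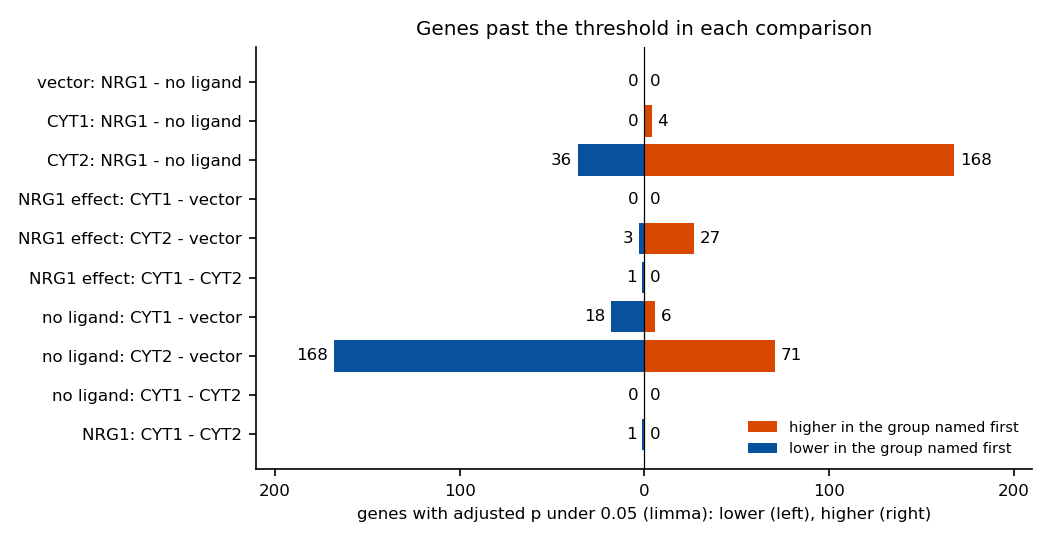
Number of genes past an adjusted p of 0.05 (limma, 12357 genes, n = 2 per group) in each of the 10 comparisons, with genes higher in the group named first to the right and genes lower in it to the left. The bars for NRG1 in CYT2 cells (168 higher, 36 lower) and for CYT2 against vector cells without ligand (71 higher, 168 lower) are the longest.

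The introduced receptor could not be followed on these arrays. The single ERBB4 probe was detected on 0 of the 16 arrays of CYT1 and CYT2 cells and on 0 of the 8 arrays of vector cells, so no fold is given and the probe checks nothing about the line labels. Among the other members of the receptor family, EGFR lay at a log2 intensity of 9.74, 9.73 and 9.45 in vector, CYT1 and CYT2 cells without ligand, and ERBB2 at 8.98, 8.92 and 9.01. ERBB3 was dimmer, at 6.2, 5.87 and 6.14, but was detected on 4 of 4 arrays in each group, vector cells included. EGFR, ERBB2 and ERBB3 did not pass in any comparison. The lowest log2 change among them was -0.40 ± 0.16 (SE, n = 2 against 2) for ERBB3 with NRG1 in CYT2 cells, where its other probe gave -0.01, with an adjusted p of 0.36 (limma).

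In vector cells, which asks what NRG1 does without introduced ERBB4, 0 of 12357 genes passed with limma, and the smallest adjusted p was 0.245. At an unadjusted p under 0.05 there were 500 genes, against 618 that chance alone gives. The genes with the smallest p did not pass. ORC4, a subunit of the origin recognition complex detected on 2 of 4 arrays without ligand, had a log2 change of 0.67 ± 0.10, CCNI2, detected on 3 of 4 arrays with NRG1, of -0.62 ± 0.12 (other probe -0.09) and MMP10, a secreted metalloproteinase not detected on any array with NRG1, lay at least 1.16-fold lower (n = 2 against 2). None of the 20 lists tested passed. The ERK pathway feedback genes had a median log2 change of 0.00 and the immediate-early genes of -0.03, with 0 of 22 measured members past the threshold in each, also when adjusted over the list alone. Among the inflammatory and NF-kB target genes 1 of 17 rose when adjusted over the list alone, and 0 over all genes.

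In CYT1 cells 4 genes rose past the threshold with NRG1 and none fell past it. They were GJB2, a gap junction connexin, by 0.82 ± 0.10 (1.76-fold), MMP3, a matrix-degrading protease detected on 3 of 4 arrays without ligand, by 0.79 ± 0.12, TGFA, a ligand of the EGF receptor, by 0.77 ± 0.11, and MAP3K9, a kinase upstream of JNK, by 0.76 ± 0.10 (SE, n = 2 against 2). Their adjusted p-values in limma were 0.0411, 0.0496, 0.0496 and 0.0463. All were higher in both samples with NRG1 than in both without. At an unadjusted p under 0.05 there were 933 genes, 545 of them higher and 388 lower. FBXO32, chosen after its value was seen, had a larger log2 change of -1.01 ± 0.16 and did not pass (limma adjusted p = 0.081).

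Of 22 measured ERK pathway feedback genes 0 passed in CYT1 cells over all genes and 8 rose when adjusted over the list alone, with a median log2 change of 0.36 (camera adjusted p = 1.1e-09, and adjusted p = 0.17 with an estimated correlation). Immediate-early genes had 0 of 22 and 7 adjusted over the list alone, with a median of 0.32 (adjusted p = 0.40 with an estimated correlation). Inflammatory and NF-kB target genes had 0 of 17 and 7 adjusted over the list alone, with a median of 0.37 (adjusted p = 0.40 with an estimated correlation). TGFA was the 1 of 7 ERBB receptors and ligands to rise, against 3 adjusted over the list alone (adjusted p = 0.17 with an estimated correlation). Further lists passed camera without a member past the threshold over all genes. The medians were 0.17 for 15 YAP and TEAD target genes (4 rose adjusted over the list alone), 0.18 for 13 epithelial adhesion genes, 0.20 for 9 basal keratinocyte-type genes and -0.12 for 25 mitosis genes (0 adjusted over the list alone in these 3), each with an adjusted p = 0.40 with an estimated correlation. The count of 4 genes moved with the processing and with single samples. It was 0 (limma) on the authors' unnormalized value table, without a filter on dim probes, on either set of technical arrays alone, with only these groups in the fit and with all probes tested, but 57 with all 24 arrays and the biological sample as a random block, 10 with the replicate block and 7 with trend and robust in eBayes. It was 0 without CYT1 sample 1 with NRG1, 69 (29 higher and 40 lower, with 3 of the 4 among them) without sample 2 with NRG1, 0 without sample 1 and 1 without sample 2 of CYT1 cells without ligand.

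In CYT2 cells NRG1 changed 204 genes, of which 168 rose and 36 fell. The chemokine CXCL8 rose most, by 2.95 ± 0.40 on the log2 scale (7.75-fold, limma adjusted p = 0.0034), followed by MMP3, detected on 3 of 4 arrays without ligand, at 2.56 ± 0.12 (5.88-fold, adjusted p = 3.36e-07), SPRY4, an inhibitor of receptor tyrosine kinase signalling, at 2.11 ± 0.26 (other probe 0.79), and the epithelial cytokine IL36G at 1.98 ± 0.24, which was detected on 2 of 4 arrays without ligand. HBEGF, a ligand of EGFR and ERBB4, rose by 1.86 ± 0.37, the pseudokinase TRIB1 by 1.86 ± 0.26, the ERK phosphatase DUSP6 by 1.66 ± 0.32 and the matricellular protein CCN2 by 1.60 ± 0.29 (SE, n = 2 against 2). The largest fall was that of FBXO32, a ubiquitin ligase subunit known from muscle atrophy, by -1.36 ± 0.16 (adjusted p = 0.0014), with its other probe at -0.60. VAV3 fell by -1.28 ± 0.23, CHN1, a GTPase activator for Rac, by -0.91 ± 0.13, the luminal transcription factor GATA3 by -0.86 ± 0.14 and TXNIP, an inhibitor of thioredoxin, by -0.83 ± 0.13. SESN2 fell by -0.82 ± 0.15 and TENT5B by -0.82 ± 0.17. SMAD6, an inhibitor of bone morphogenetic protein signalling that was not detected with NRG1, was at least 1.52-fold lower.

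**Figure D2:**
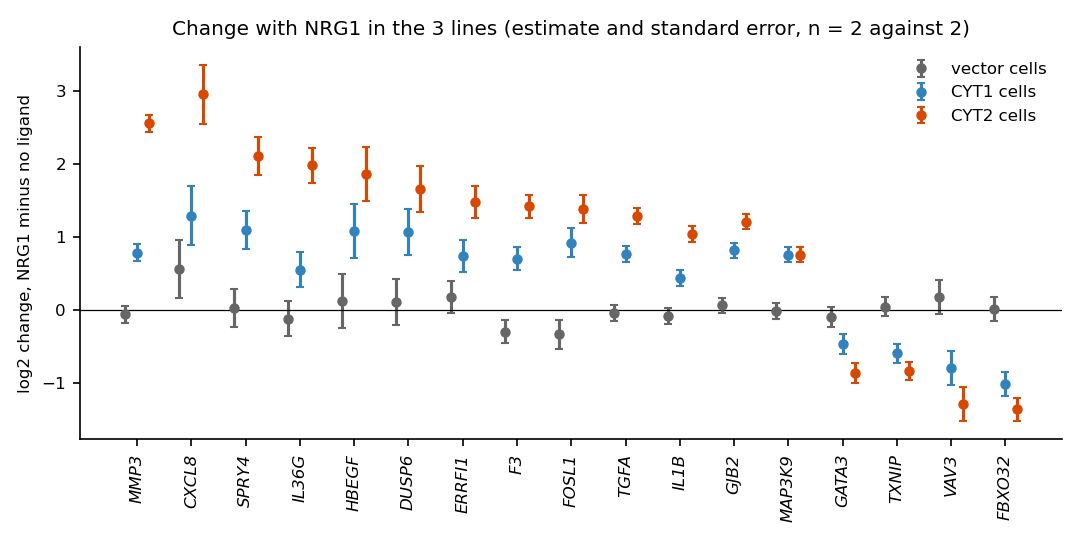
Change of 17 named genes with NRG1 in vector, CYT1 and CYT2 cells, as the log2 difference between samples with and without NRG1 (points) with the standard error of the fit (bars), n = 2 against 2. MMP3 lay at -0.06 in vector, 0.79 in CYT1 and 2.56 in CYT2 cells, and FBXO32 at -1.36 in CYT2 cells.

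ERK pathway feedback genes, a list that besides inhibitors holds genes such as the urokinase receptor PLAUR and the receptor kinase EPHA2, had the most members past the threshold in CYT2 cells. Of 22 measured, 11 rose over all genes and 15 adjusted over the list alone. The median was 0.74 (camera adjusted p = 1.4e-18, and adjusted p = 0.078 with an estimated correlation). Besides SPRY4 and DUSP6 those that rose included ERRFI1, an inhibitor of EGFR family kinases, at 1.48 ± 0.22 and DUSP4 at 1.33 ± 0.28, whose other probe gave 0.33. Of 17 inflammatory and NF-kB target genes 6 rose and 11 did when adjusted over the list alone, with a median of 0.90 and all 17 above 0 (adjusted p = 0.11 with an estimated correlation). Among them were TNFAIP3, which restrains NF-kB, at 1.57 ± 0.29, CXCL2 at 1.16 ± 0.24 and IL1B at 1.04 ± 0.11. Of 22 immediate-early genes 5 rose, with FOSL1, an AP-1 subunit, at 1.38 ± 0.20, KLF6 at 1.31 ± 0.17, MAFF at 1.30 ± 0.21 (other probes 0.67 and 1.03) and MCL1 at 0.74 ± 0.12. Adjusted over the list alone 12 rose and 1 fell. The median was 0.64 (adjusted p = 0.28 with an estimated correlation). Of 7 ERBB receptors and ligands 4 rose, namely HBEGF, TGFA at 1.29 ± 0.11, EREG at 0.91 ± 0.18 and NRG1 itself at 0.62 ± 0.13, whose other probes gave 0.39 and 0.06. Adjusted over the list alone 4 rose and 1 fell (adjusted p = 0.078 with an estimated correlation).

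Smaller groups followed in CYT2 cells. Of 15 YAP and TEAD target genes CCN2 and F3, the initiator of coagulation, rose, F3 by 1.42 ± 0.16, while 5 rose and 1 fell adjusted over the list alone (adjusted p = 0.35 with an estimated correlation). Of 15 keratinocyte differentiation genes SPRR2A (1.17 ± 0.21) and PI3 (0.53 ± 0.10) rose, 2 also adjusted over the list alone, with a median of 0.16 (adjusted p = 0.48 with an estimated correlation). The mitosis genes had a median of -0.20, with 0 of 25 past the threshold over all genes and 5 lower adjusted over the list alone (adjusted p = 0.30 with an estimated correlation). E2F2, at -0.80 ± 0.14, was the 1 of 24 DNA replication genes that fell, over all genes and adjusted over the list alone (median -0.10, adjusted p = 0.38 with an estimated correlation).

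The remaining lists did not pass camera for NRG1 in CYT2 cells. Of 12 luminal mammary genes FOXA1 rose by 1.03 ± 0.16 and GATA3 fell, and adjusted over the list alone 2 rose and 1 fell. HK2 (0.58 ± 0.09) and PFKFB3 (0.63 ± 0.11), both of glycolysis, rose among 17 hypoxia genes, 2 also adjusted over the list alone. SESN2 fell among 12 amino acid and ER stress response genes, where 3 rose and 4 fell adjusted over the list alone. SESN1, at -0.65 ± 0.11, fell among 12 p53 target genes, 1 also adjusted over the list alone. SNAI2 rose by 0.79 ± 0.15 among 11 mesenchymal genes, 1 also adjusted over the list alone. No member passed over all genes among 9 STAT5 target and milk genes (1 rose and 1 fell adjusted over the list alone), 9 basal keratinocyte-type genes (1 rose adjusted over the list alone), 20 genes of cholesterol synthesis and uptake, 11 of fatty acid synthesis, 21 interferon-stimulated genes, 13 epithelial adhesion genes and 5 fibroblast markers (0 adjusted over the list alone in each of these 5 lists). Only 2 immune and endothelial markers were measured, with a median of -0.09, and the list was not tested.

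The number of genes depended on the fit and on single samples. With only the CYT2 samples in the fit 9 genes passed, and leaving out a sample left 155 (without sample 1 without ligand), 28 (without sample 2 without ligand), 58 (without sample 1 with NRG1) or 114 genes (without sample 2 with NRG1). Of the 274 genes past the threshold on the authors' unnormalized value table, 99.6% were higher, against 82.4%.

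The differences of NRG1 effects between lines were tested directly. CYT2 cells differed from vector cells in 30 genes, with the more positive change in CYT2 cells in 27 and the more negative in 3. The difference was 2.61 ± 0.16 for MMP3 (limma adjusted p = 1.6e-05), 2.10 ± 0.34 for IL36G, 2.08 ± 0.37 for SPRY4 (other probe 0.77), 1.72 ± 0.22 for F3 (other probe 1.19) and 1.71 ± 0.28 for FOSL1. It was -1.37 ± 0.23 for FBXO32 (other probe -0.45), -0.90 ± 0.15 for FZD2, a Wnt receptor, and -0.79 ± 0.13 for ACTMAP (SE, n = 2 per group). The list members with such a difference were FOSL1, KLF6, DUSP5, SPRY4, PHLDA1, TGFA, F3 and IL1B. All were also lower in CYT2 than in vector cells without ligand, from -0.87 for TGFA to -1.67 for SPRY4. None passed between CYT2 and vector cells with NRG1, so their difference goes with a lower level before ligand. MMP3 was higher there, by 2.00. ERK pathway feedback genes had a median difference of 0.71, with 3 of 22 past the threshold over all genes and 12 adjusted over the list alone (adjusted p = 0.075 with an estimated correlation, fry adjusted p = 0.035). ERBB receptors and ligands had a median difference of 0.80, with 1 of 7 past the threshold, TGFA, and 4 adjusted over the list alone (adjusted p = 0.075 with an estimated correlation). Immediate-early genes had a median difference of 0.66, with 2 of 22 past the threshold and 8 adjusted over the list alone (adjusted p = 0.30 with an estimated correlation), and inflammatory and NF-kB target genes of 0.50, with 1 of 17 and 2 adjusted over the list alone (adjusted p = 0.26 with an estimated correlation). Negative medians that passed camera were -0.24 for 25 mitosis genes (adjusted p = 0.38 with an estimated correlation) and -0.21 for 11 fatty acid synthesis genes (adjusted p = 0.47 with an estimated correlation), with 0 members past the threshold, also adjusted over the list alone. The YAP and TEAD target genes (median 0.26, 1 of 15 past the threshold, F3, and 2 adjusted over the list alone) and the keratinocyte differentiation genes (median 0.17, 0 of 15 and 2 adjusted over the list alone) also passed camera. Both had an adjusted p = 0.47 with an estimated correlation. So did 11 mesenchymal genes, upward at a mean of 0.18 and a median of -0.01, with 0 past the threshold and 2 adjusted over the list alone (adjusted p = 0.36 with an estimated correlation). The count of 30 fell to 1 without sample 1 or sample 2 of vector cells with NRG1 or without sample 2 of vector cells without ligand, and was 10 without sample 1 of the latter. Leaving out CYT2 samples gave 47 and 6 (samples 1 and 2 without ligand) and 6 and 18 (samples 1 and 2 with NRG1).

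Between CYT1 and vector cells 0 genes differed in their NRG1 effect with limma, at a smallest adjusted p of 0.546 and with 734 genes at an unadjusted p under 0.05. FBLIM1 (1.13 ± 0.21, other probe 0.59), TGFA (0.81 ± 0.16) and MAP3K9 (0.77 ± 0.15) had the smallest p and did not pass. ERK pathway feedback genes had a median difference of 0.42, with 0 of 22 past the threshold and 2 adjusted over the list alone (adjusted p = 0.29 with an estimated correlation). Camera also passed, with 0 members past the threshold over all genes, immediate-early genes (median 0.34, 3 adjusted over the list alone), inflammatory genes (0.30, 0 adjusted over the list alone), basal keratinocyte-type genes (0.29, 0 adjusted over the list alone) and mitosis genes (-0.22, 0 adjusted over the list alone). Each had an adjusted p = 0.58 with an estimated correlation. The ERBB receptors and ligands (0.38, 1 adjusted over the list alone, adjusted p = 0.28 with an estimated correlation) and epithelial adhesion genes (0.24, 0 adjusted over the list alone, adjusted p = 0.55 with an estimated correlation) did so too. Between the isoforms 1 gene differed, MMP3, whose rise was smaller in CYT1 than in CYT2 cells by a log2 difference of -1.77 ± 0.16 (limma adjusted p = 0.0015, n = 2 per group). LRRC8C (-0.78 ± 0.16) and ADI1 (-0.65 ± 0.14) came next and did not pass, and 447 genes had an unadjusted p under 0.05. ERK pathway feedback genes had a median difference of -0.30 between CYT1 and CYT2 cells, with 0 of 22 past the threshold, also adjusted over the list alone (adjusted p = 0.66 with an estimated correlation). Immediate-early genes (median -0.30, 0 adjusted over the list alone, adjusted p = 0.69 with an estimated correlation), inflammatory genes (-0.31, 1 adjusted over the list alone, adjusted p = 0.66 with an estimated correlation) and keratinocyte differentiation genes (-0.12, 0 adjusted over the list alone, adjusted p = 0.69 with an estimated correlation) passed camera with 0 members past the threshold over all genes. The keratinocyte list lay at a median of 0.02 without CYT2 sample 1 without ligand and no longer passed. The MMP3 call was lost on either set of technical arrays alone and with all 24 arrays and the biological sample as a random block, with 0 genes in each (limma).

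The 4 genes that rose in CYT1 cells were all among the 168 that rose in CYT2 cells, against 0.054 for independent lists. Of those 168 genes 167 had a positive change in CYT1 cells, with a median of 0.41 against 0.71 in CYT2 cells, and 88 in vector cells, with a median of 0.01. Of the 36 that fell in CYT2 cells 35 were negative in CYT1 cells, with a median of -0.36 against -0.68. Both sets were chosen by passing in these CYT2 samples, which tends to enlarge their CYT2 medians. Over 100 genes chosen on 1 CYT2 pair, the held-out CYT2 pairs rose by medians of 1 and 0.97. The CYT1 pairs rose by 0.43 to 0.69 over those genes. Across all 12357 genes, which are not independent replicates, the NRG1 changes of CYT1 and CYT2 cells correlated at r = 0.52, those of vector and CYT2 cells at 0.04 and those of vector and CYT1 cells at -0.02.

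**Figure D3:**
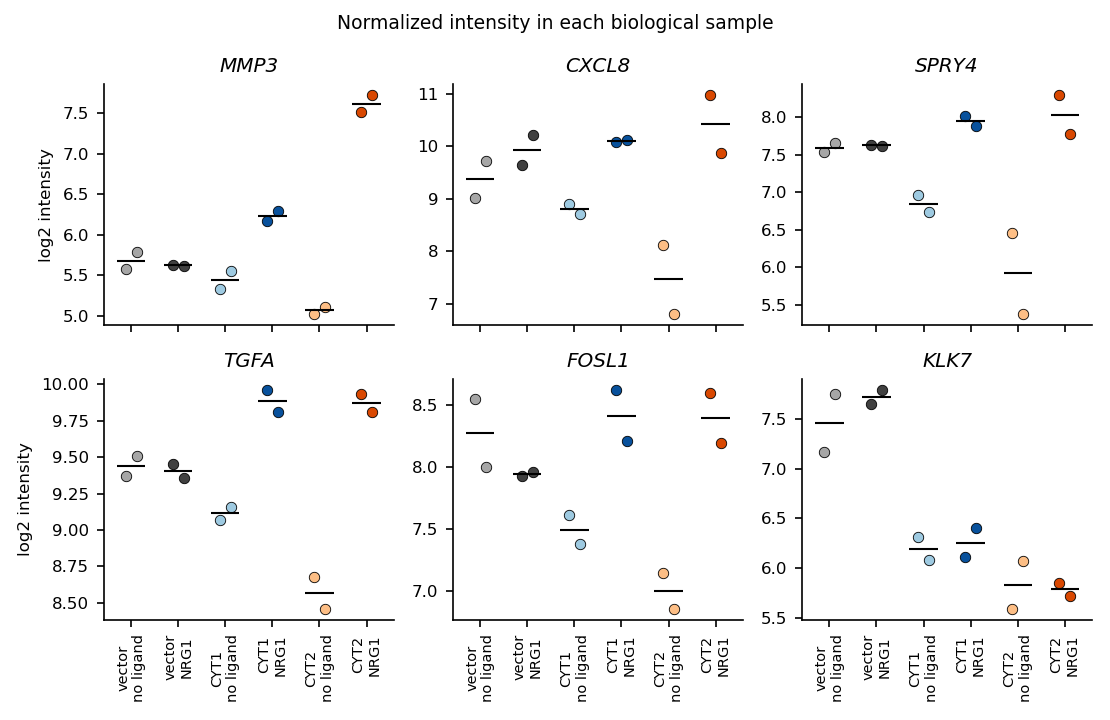
Normalized log2 intensity of 6 genes in each of the 12 biological samples, 2 per group, with the group mean as a line. MMP3 lay at 7.52 and 7.72 in CYT2 cells with NRG1 and at 6.17 and 6.29 in CYT1 cells with NRG1, and KLK7 between 5.59 and 6.40 in all CYT1 and CYT2 samples against 7.17 to 7.79 in vector samples.

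Without ligand, CYT1 cells differed from vector cells in 24 genes, of which 18 were lower. Keratins of stratified epithelia led the lower genes, with KRT1 at -1.98 ± 0.32 (3.94-fold, limma adjusted p = 0.029), KRT4 at -1.82 ± 0.29 and KRT13 at -1.63 ± 0.14, the last detected on 2 of 4 CYT1 arrays (SE, n = 2 against 2). The vitamin B12 binding protein TCN1, also detected on 2 of 4 arrays, was lower by -1.54 ± 0.22, the skin protease KLK7 by -1.27 ± 0.19, IGFL1 by -1.27 ± 0.21 and GPRC5A by -1.10 ± 0.16. KLK10 was lower by -1.14 ± 0.18, although its other probe gave 0.14. Higher in CYT1 cells were POGLUT3, a protein glucosyltransferase detected on 3 of 4 vector arrays, by 1.0 ± 0.11, the peroxisomal oxidase ACOX2 by 0.94 ± 0.16, KIR2DL4 by 0.84 ± 0.13, TMT1A by 0.82 ± 0.12 and SLC6A15, an amino acid transporter, by 0.66 ± 0.10 (other probes 0.33 and 0.17). DPYSL4, which was not detected in vector cells, was at least 1.48-fold higher.

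By list, 3 of 15 keratinocyte differentiation genes fell in CYT1 cells relative to vector cells (KRT1, KLK7 and KLK5, the last by -1.09 ± 0.17), while 10 fell and 1 rose adjusted over the list alone, with a median of -0.34 (adjusted p = 0.31 with an estimated correlation). Of 13 epithelial adhesion genes CLDN7, a tight junction protein, fell by -0.79 ± 0.13, and 5 fell adjusted over the list alone (adjusted p = 0.24 with an estimated correlation). F3 (-0.92 ± 0.16, other probe -0.14) and IL1B (-0.67 ± 0.11) fell, the 1 member each of the YAP and TEAD and the inflammatory lists to do so. Adjusted over the list alone 2 fell and 1 rose among the YAP and TEAD genes, and 1 fell among the inflammatory genes (adjusted p = 0.55 with an estimated correlation). No immediate-early or ERK pathway feedback gene passed over all genes, while 6 and 4 of 22 fell adjusted over the list alone, with medians of -0.40 (adjusted p = 0.32 with an estimated correlation) and -0.34 (adjusted p = 0.24 with an estimated correlation). Mitosis genes had a median of 0.22, with 0 of 25 past the threshold and 9 higher adjusted over the list alone (adjusted p = 0.24 with an estimated correlation). ERBB receptors and ligands (median -0.33, adjusted p = 0.24 with an estimated correlation) and basal keratinocyte-type genes (-0.22, adjusted p = 0.48 with an estimated correlation) passed camera with 0 members past the threshold, also adjusted over the list alone. The count of 24 was 1 and 2 without CYT1 sample 1 or 2, and 15 and 64 without vector sample 1 or 2. The 64 were 35 higher and 29 lower, and 12 of the 24 were among them. No gene passed on the authors' unnormalized value table.

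Without ligand, CYT2 cells differed from vector cells in 239 genes, 168 lower and 71 higher. The lowest were KRT4 at -2.39 ± 0.29 (5.23-fold, limma adjusted p = 0.0024) and KRT1 at -2.04 ± 0.32. HBEGF was lower by -1.94 ± 0.37, IL36G, detected on 2 of 4 CYT2 arrays, by -1.91 ± 0.24 and CXCL8 by -1.89 ± 0.40. Below detection on all CYT2 arrays were KRT13 (at least 3.03-fold lower), TCN1 (at least 2.97-fold lower) and the immediate-early transcription factor EGR3 (at least 2.9-fold lower). Higher in CYT2 cells were ACOX2 by 1.16 ± 0.16, KIR2DL4 by 1.13 ± 0.13, POGLUT3 by 1.07 ± 0.11, the glycine cleavage enzyme GLDC by 0.88 ± 0.18, the co-receptor NRP2 by 0.82 ± 0.12, with other probes at 0.24, -0.13 and 0.28, the protease CTSK by 0.78 ± 0.12, detected on 1 of 4 vector arrays, and SERPINE2 by 0.73 ± 0.14. PADI4, which was not detected in vector cells, was at least 1.53-fold higher (SE, n = 2 against 2).

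Of 22 immediate-early genes 8 fell in CYT2 cells relative to vector cells without ligand, among them MAFF (-1.37 ± 0.21, other probes -0.29 and -0.67), KLF6 (-1.29 ± 0.17) and FOSL1 (-1.27 ± 0.20). Adjusted over the list alone 15 fell, with a median of -0.71 (adjusted p = 0.17 with an estimated correlation). ERK pathway feedback genes fell in 7 of 22, with SPRY4 at -1.67 ± 0.26 (other probe -0.31), PLAUR at -1.23 ± 0.23 (other probes -0.10 and -1.17), DUSP5 at -1.20 ± 0.16 and ERRFI1 at -1.10 ± 0.22. Adjusted over the list alone 15 fell, with a median of -0.65 (adjusted p = 0.099 with an estimated correlation). Inflammatory and NF-kB target genes fell in 2 of 17, CXCL8 and IL1B (-1.01 ± 0.11), and in 10 adjusted over the list alone (adjusted p = 0.18 with an estimated correlation). HBEGF and TGFA (-0.87 ± 0.11) fell among 7 ERBB receptors and ligands, 3 adjusted over the list alone (adjusted p = 0.099 with an estimated correlation).

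Of 15 keratinocyte differentiation genes 5 fell in CYT2 cells relative to vector cells, with KLK7 at -1.64 ± 0.19, KLK5 at -1.56 ± 0.17 and KRT10 at -1.11 ± 0.18. In all 11 fell and 1 rose adjusted over the list alone, with a median of -0.38 (adjusted p = 0.17 with an estimated correlation). CLDN7 (-0.93 ± 0.13) and the desmosomal cadherin DSC2 (-0.65 ± 0.15) fell among 13 epithelial adhesion genes, 7 falling and 1 rising adjusted over the list alone (adjusted p = 0.19 with an estimated correlation). Mitosis genes rose in 6 of 25, among them CENPA, the centromeric histone, by 0.67 ± 0.14 (other probe 0.36), the kinases TTK by 0.58 ± 0.11, PLK1 by 0.54 ± 0.11 and AURKA by 0.49 ± 0.09. When adjusted over the list alone 19 rose, with a median of 0.36 (adjusted p = 0.12 with an estimated correlation). CCN2 (-1.44 ± 0.29), F3 (-1.35 ± 0.16, other probe -0.83) and GADD45A (-0.71 ± 0.15) fell among 15 YAP and TEAD target genes, where 4 fell and 2 rose adjusted over the list alone. The count of 239 was 133 and 80 without vector sample 1 or 2, and 82 and 130 without CYT2 sample 1 or 2. On the authors' unnormalized value table it was 38.

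In other lists single members passed for CYT2 against vector cells. DDIT4, an inhibitor of mTOR signalling, rose by 0.45 ± 0.10 among 12 amino acid and ER stress response genes, 4 adjusted over the list alone (median 0.25, adjusted p = 0.21 with an estimated correlation). FOXA1 fell by -0.93 ± 0.16 among 12 luminal mammary genes, 1 also adjusted over the list alone (median -0.13, adjusted p = 0.15 with an estimated correlation), and TWIST1 by -0.54 ± 0.11 among 11 mesenchymal genes, 1 also adjusted over the list alone (median -0.05, adjusted p = 0.21 with an estimated correlation). PIM1, a kinase induced by STAT5, fell by -1.65 ± 0.33 among 9 STAT5 target and milk genes (1 rose and 1 fell adjusted over the list alone), PFKFB3 by -0.47 ± 0.11 among 17 hypoxia genes (1 adjusted over the list alone), and SESN1 rose by 0.53 ± 0.11 among 12 p53 target genes (1 rose and 1 fell adjusted over the list alone), in lists that did not pass camera. Basal keratinocyte-type genes (median -0.24, adjusted p = 0.26 with an estimated correlation) and interferon-stimulated genes (median -0.15, adjusted p = 0.35 with an estimated correlation) passed camera with 0 members past the threshold, also adjusted over the list alone.

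**Figure D4:**
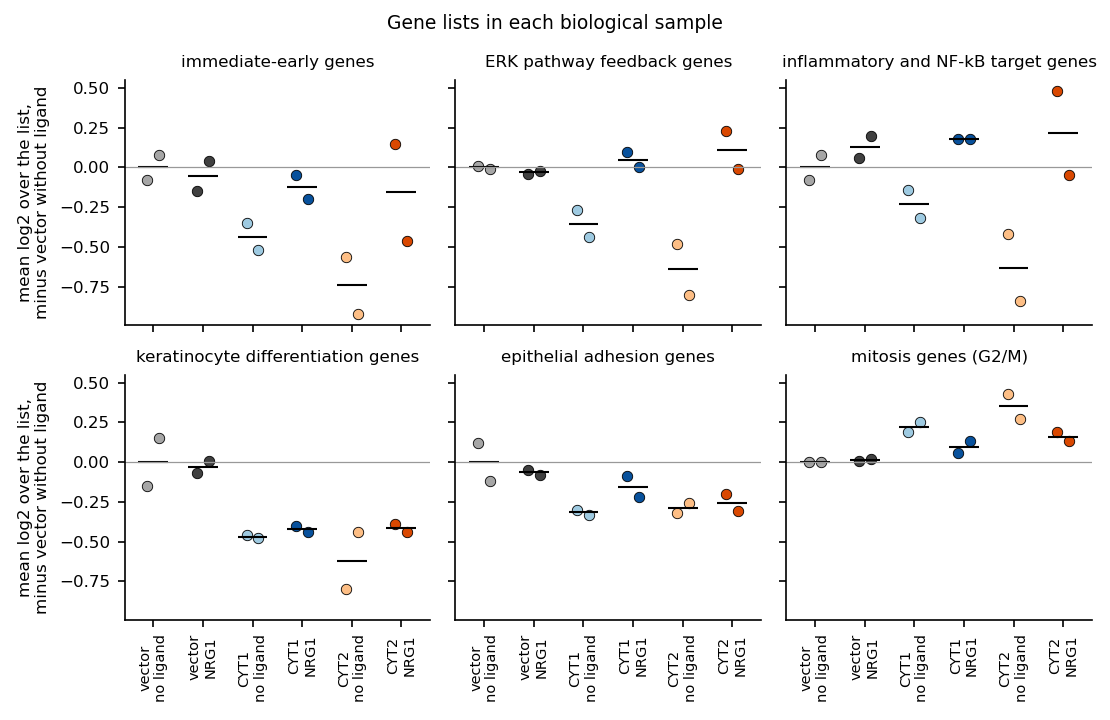
Mean log2 intensity over the measured genes of 6 lists in each of the 12 biological samples, relative to the mean of vector cells without ligand, with the group mean as a line. Immediate-early genes lay at -0.56 and -0.92 in CYT2 cells without ligand and at 0.15 and -0.46 with NRG1, and mitosis genes at 0.43 and 0.27 in CYT2 cells without ligand.

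Both ERBB4 lines were compared with the same vector samples. All 18 genes lower in CYT1 cells were among the 168 lower in CYT2 cells, against 0.24 for independent lists, and 4 of the 6 higher genes were shared, against 0.034. Unchanged groups simulated against shared controls gave at most 0 shared calls in 100 draws. Without changed genes hardly any call arises, so that count does not weigh on the overlap. The log2 changes correlated at r = 0.75 across genes, against 0.50 in the simulation, and their covariance was 0.034 against 0.0086. The controls were not split, since a split leaves 1 vector sample on each side, and part of the excess may come from the shared controls. The simulation gave every group 1 common spread per gene. The vector samples without ligand differed by 0.243 (root mean square log2 difference), where the other groups gave 0.158 to 0.255. So the simulated values may understate the part that comes from shared controls.

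Set directly against each other without ligand, CYT1 and CYT2 cells differed in 0 genes with limma, at a smallest adjusted p of 0.774 and with 682 genes at an unadjusted p under 0.05. IL36G (1.34 ± 0.24), TGFA (0.54 ± 0.11) and THBD, thrombomodulin (0.48 ± 0.09), had the smallest p and did not pass. ERK pathway feedback genes had a median of 0.24 in CYT1 relative to CYT2 cells, with 0 of 22 past the threshold and 4 adjusted over the list alone (adjusted p = 0.45 with an estimated correlation). Camera also passed, with 0 members past the threshold, also adjusted over the list alone, immediate-early genes (median 0.33), inflammatory genes (0.27), mitosis genes (-0.12), DNA replication genes (-0.11) and amino acid and ER stress response genes (-0.09). Each had an adjusted p = 0.45 with an estimated correlation. Keratinocyte differentiation genes passed likewise (0.15, adjusted p = 0.53 with an estimated correlation). The last lay at -0.05 without CYT2 sample 1 without ligand and no longer passed. With NRG1, 1 gene differed, and no list passed camera. MMP3 was lower in CYT1 than in CYT2 cells by -1.39 ± 0.12 (2.62-fold, limma adjusted p = 0.00043, n = 2 against 2), while COXFA4L3 (-0.62 ± 0.11) and MMP10 (-0.57 ± 0.11, detected on 1 of 4 CYT1 arrays) did not pass, and 812 genes had an unadjusted p under 0.05. Without sample 2 of CYT1 cells with NRG1 the count was 81 (34 higher and 47 lower), with MMP3 among them. On either set of technical arrays alone, with only these groups in the fit, or with all 24 arrays and the biological sample as a random block, it was 0 (limma).

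After NRG1 the ERBB4 lines still differed from vector cells with NRG1, in 2 comparisons added after the data were seen. In CYT1 cells KLK7 (-1.47 ± 0.19, limma adjusted p = 0.0338) and KRT13 (-1.37 ± 0.14) were lower and no gene was higher, with 1113 genes at an unadjusted p under 0.05. This count of 2 was 0 without background correction, on the authors' value table and without a filter on dim probes (limma), 0 without vector sample 2 with NRG1, 1 without CYT1 sample 1 and 255, of which 33.7% were higher, without CYT1 sample 2 with NRG1. In CYT2 cells 34 genes were lower and 15 higher. The 49 became 20 and 4 without vector sample 1 or 2 with NRG1 and 16 and 4 without CYT2 sample 1 or 2 with NRG1, and 8 genes passed on the authors' unnormalized value table, 62.5% of them higher against 30.6%. Chosen after their values were seen, the lower genes included KRT4 (-2.02 ± 0.29), KRT1 (-1.95 ± 0.32), KLK7 (-1.93 ± 0.19) and KRT13, which was not detected in CYT2 cells with NRG1 (at least 3.1-fold lower), and the higher ones MMP3 (2.00 ± 0.12), the alarmin IL33 (1.26 ± 0.16) and KIR2DL4 (1.16 ± 0.13), n = 2 against 2. Keratinocyte differentiation genes fell in 4 of 15 and in 5, with 3 rising, adjusted over the list alone (adjusted p = 0.62 with an estimated correlation). In CYT1 cells 1 of the 15 fell, KLK7, and 6 fell and 1 rose adjusted over the list alone (adjusted p = 0.83 with an estimated correlation). No immediate-early gene and no ERK pathway feedback gene passed over all genes in CYT2 cells. The latter had a median of 0.20 there, with 1 lower adjusted over the list alone (adjusted p = 0.62 with an estimated correlation). Other lists that passed camera there were mitosis (median 0.13, 0 of 25 past the threshold, also adjusted over the list alone), interferon-stimulated (-0.08, 1 of 21 lower, 2 adjusted over the list alone) and epithelial adhesion genes (-0.18, 1 of 13 lower, 1 rising and 1 falling adjusted over the list alone). Each had an adjusted p = 0.62 with an estimated correlation. Hypoxia genes (0.06, 0 of 17, 2 higher adjusted over the list alone) and luminal mammary genes (-0.14, 0 of 12, 3 lower adjusted over the list alone) passed as well. Both had an adjusted p = 0.59 with an estimated correlation.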

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

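The differences of NRG1 effects between lines, and their list tests with camera, were planned. Using the isoform comparison and the mitosis list to weigh an explanation was chosen after the result was seen, as was the overlap of 67 genes. The other tests of explanations in this section were set after their pattern was seen but before their own values were. The one on genes chosen in CYT1 cells was set only once the one on genes chosen in CYT2 cells was known. Groups of 2 samples are too small for a test of single samples against their group, so none was made.

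The effect of NRG1 differed between CYT2 and vector cells, by a test of the difference itself, in 30 genes, led by MMP3 (2.61), IL36G (2.10), SPRY4 (2.08, other probe 0.77), F3 (1.72) and FOSL1 (1.71) upward and FBXO32 (-1.37, other probe -0.45), FZD2 (-0.90) and ACTMAP (-0.79) downward on the log2 scale. Of these, SPRY4, F3 and FOSL1 lay below vector cells without ligand (-1.67, -1.35 and -1.27) and did not pass against vector cells with NRG1. The lists of ERK pathway feedback genes (median difference 0.71) and ERBB receptors and ligands (0.80) differed with camera at a preset correlation and with fry, and not with an estimated correlation (adjusted p = 0.075 for both). Between CYT1 and CYT2 cells the effect of NRG1 differed in 1 gene, MMP3 (-1.77), and in 0 on either set of technical arrays alone or with all 24 arrays and the biological sample as a random block (limma, 447 genes at an unadjusted p under 0.05 in the fit that called MMP3). Among probes without a gene name, which enter no comparison of genes, 25 of 6399 passed for NRG1 in CYT2 cells, 2 for the difference between CYT2 and vector cells, 2 for CYT1 against vector cells and 34 for CYT2 against vector cells without ligand (limma).

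For NRG1, 204 genes passed the threshold in CYT2 cells and 4 in CYT1 cells. The fit pooled the spread over all groups, so a gene had the same standard error in both lines (0.11 for TGFA in each). A wide spread between the CYT1 samples was weighed as the whole reason by the size of the rises. Over 100 genes chosen by their rise in 1 pair of CYT2 samples, the held-out CYT2 pairs rose by medians of at least 0.97. Every CYT1 sample pair lay below that, the highest at 0.69. List means were set against vector cells without ligand. ERK pathway feedback genes lay at -0.27 and -0.44 in CYT1 and -0.48 and -0.80 in CYT2 samples without ligand. With NRG1 they lay at 0.10 and 0.00, and at 0.23 and -0.01. No gene passed between these lines without ligand, and only MMP3 did with NRG1. In this list the larger CYT2 rise went with a lower level before ligand rather than a clearly higher one after it. The CYT1 count was 69 (29 higher and 40 lower, with 3 of the 4 among them) without CYT1 sample 2 with NRG1, 0 without sample 1 with NRG1, and 0 and 1 without sample 1 or 2 without ligand, while that of CYT2 cells was 155 and 28 without sample 1 or 2 without ligand and 58 and 114 without sample 1 or 2 with NRG1, and the cause was not tested. A CYT1 response over other genes was tested for rises only. Genes chosen on 1 CYT1 pair rose by 0.35 and 0.12 in the held-out CYT1 pair, where the CYT2 pairs gave 0.62 to 0.97 and 0.22 to 0.26. So the genes that rose most in a CYT1 pair rose more in CYT2 cells. The value of 0.12 rests on genes chosen with CYT1 sample 1 with NRG1, which stood apart. Falls were not tested, and medians over 100 genes cannot exclude a CYT1 response over fewer genes. A difference between the isoforms remains open as a hypothesis, because with 1 line per isoform the 1 gene past its test cannot be told apart from a difference between lines, such as in the amount of receptor, on which the undetected ERBB4 probe gives no value.

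Genes that rose with NRG1 in CYT2 cells lay below vector cells before the ligand. Of the 168 that rose, 67 were among the 168 lower than vector cells, against 2.3 for independent lists. With NRG1 these 67 genes lay at a median of 0.13 against vector cells with NRG1, and 3 of them passed there (limma). The comparisons that gave these 67 genes share the CYT2 samples without ligand, and part of the excess may come from those samples. The covariance across genes was -0.027, against -0.0086 in 100 simulated draws of unchanged groups. Those draws gave at most 0 shared calls, which without changed genes does not weigh on the overlap. As the whole reason that sharing is argued against, since over genes chosen on 1 pair the held-out CYT2 sample lay at medians of -1.04 and -0.57 against vector cells. A single vector sample is argued against too, the value nearest to 0 against 1 of them being -0.53. Over the same genes CYT1 cells without ligand also lay below vector cells, at -0.45 and -0.33. The held-out CYT2 sample with NRG1 lay at -0.03 and 0.41 against vector cells without ligand. A different growth state of the CYT2 cultures stays open, with mitosis genes at a median of 0.36 above vector cells (adjusted p = 0.12 with an estimated correlation), and cannot be told apart from an effect of the receptor because each construct was carried by 1 line.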

How the results depend on the processing

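Leaving out the second array of CYT1 sample 2 without ligand and fry were chosen after the result was seen, as were the gene lists with samples left out or without background correction; the other alternatives were planned. The 110 values of named genes past the threshold kept their direction under every alternative run. That was largely fixed by the choice, since all 110 had passed in these data and the largest changes were taken from groups without overlap. Of the 110, 17 stayed past the threshold under all alternatives except leaving out a sample, and 14 under all. For NRG1 in vector cells and for the difference of NRG1 effects between CYT1 and vector cells 0 genes passed under every alternative (limma). Where a count moved, the cause was not tested, except that fewer samples, or more genes tested, were part of the alternative itself. Signal over background limits the dim genes, such as ERBB4, which was detected on 0 arrays. The chip as a block was not run, since the files name no chips.

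Counts of genes past the threshold are given as genes in total. Without background correction CYT1 against vector cells without ligand gave 79 (38.0% higher, against 25.0%), and CYT2 against vector cells 328 (40.2% higher, against 29.7%). On the authors' unnormalized value table NRG1 in CYT1 cells gave 0, the difference of NRG1 effects between CYT2 and vector cells 5, CYT1 against vector cells 0 and CYT2 against vector cells 38, and 99.6% of 274 calls for NRG1 in CYT2 cells were higher. There the median over all genes was 0.105 for NRG1 in CYT2 cells, 0.107 for CYT1 against vector cells and -0.101 for the difference between CYT1 and CYT2 cells. Without a filter on dim probes NRG1 gave 0 in CYT1 and 132 in CYT2 cells, the difference between CYT2 and vector cells 12 and CYT1 against vector cells 3.

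On the first technical arrays alone NRG1 gave 0 in CYT1 and 122 in CYT2 cells, the difference between CYT2 and vector cells 14, that between CYT1 and CYT2 cells 0, CYT1 against vector cells 1, CYT2 against vector cells 119 and CYT1 against CYT2 cells with NRG1 0. On the second arrays alone these were 0, 85, 4, 0, 2, 71 and 0. With all 24 arrays and the biological sample as a random block they were 57, 442, 162, 0, 357, 726 and 0, with 1 for CYT1 against CYT2 cells without ligand. With trend and robust in eBayes NRG1 in CYT1 cells gave 7, the difference between CYT2 and vector cells 63 and CYT1 against vector cells 60. With only the groups compared in the fit NRG1 gave 0 in CYT1 and 9 in CYT2 cells, the difference between CYT2 and vector cells 16, CYT1 against vector cells 8, CYT2 against vector cells 148 and CYT1 against CYT2 cells with NRG1 0. With all probes tested NRG1 in CYT1 cells gave 0, and at a fold of at least 1.5 CYT2 against vector cells gave 153. The 2 added comparisons against vector cells with NRG1 moved too. For CYT1 cells, 2 genes became 0 without background correction, on the authors' value table and without a filter on dim probes, 10 with detection asked on all arrays of a group, 4 and 1 on the first and second arrays alone, 87 with 24 arrays and a random block, 15 with the replicate block and 22 with trend and robust. For CYT2 cells, 49 became 8 on the authors' value table, 20 without a filter on dim probes, 32 and 23 on the first and second arrays and 195 with 24 arrays.

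Over all genes, replicate numbers showed no clear pairing of the samples, since the 15 correlations of deviations between groups ran from -0.17 to 0.23. Between samples with and without NRG1 they were 0.23 in vector, -0.17 in CYT1 and 0.18 in CYT2 cells. Single lists varied in CYT2 cells. Inflammatory and NF-kB target genes had means of -0.42 and -0.84 in samples 1 and 2 without ligand. With NRG1 these were 0.48 and -0.05, each relative to vector cells without ligand. Keratinocyte differentiation genes lay at -0.80 and -0.44, and at -0.39 and -0.44. So pairing among genes that respond is not excluded. A pairing within each line was not modelled, only a block common to all lines, so an offset shared by such a pair counted as spread. With the replicate number as a block NRG1 in CYT1 cells gave 10 genes and the difference between CYT2 and vector cells 46, and 62 of 63 gene list results kept their side of the threshold. Of these 63, 62 also passed without background correction and 59 on the authors' value table, while camera with an estimated correlation kept 0 and fry 14.

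Leaving out 1 biological sample at a time, with the lone sample assumed to vary like the other groups, gave 0 to 69 genes for NRG1 in CYT1 cells, 28 to 155 for NRG1 in CYT2 cells, 1 to 47 for the difference between CYT2 and vector cells, 1 to 64 for CYT1 against vector cells, 80 to 133 for CYT2 against vector cells and 1 to 81 for CYT1 against CYT2 cells with NRG1. The highest NRG1 count in CYT1 cells (69) and that of 81 came without CYT1 sample 2 with NRG1, the 28 without CYT2 sample 2 and the 47 without CYT2 sample 1 without ligand, the 64 without vector sample 2 without ligand. Without CYT2 sample 1 without ligand the keratinocyte differentiation genes turned their direction and no longer passed. For the difference between CYT1 and CYT2 cells and for CYT1 against CYT2 cells without ligand, the camera adjusted p of this list was 0.02 and 0.012, and it was lost with an estimated correlation (0.69 and 0.53), on the authors' value table (0.2 and 0.22) and with fry (0.81 and 0.55). Over the samples left out, it ran from 3.7e-07 to 0.96 (without that sample) for the difference between CYT1 and CYT2 cells, and from 8.9e-09 to 0.78 (without that sample) for CYT1 against CYT2 cells without ligand, and the cause was not tested.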

Other observations

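The tests of FOXO target genes were chosen after the result was seen, and so were the genes named in the next paragraph.

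Further genes that rose with NRG1 in CYT2 cells lay outside the lists (limma, n = 2 against 2). On the log2 scale the cytokine IL24, detected on 2 of 4 arrays without ligand, rose by 1.54 ± 0.17, the glucose transporter SLC2A3 by 1.46 ± 0.26, the hyaluronan synthase HAS3 by 1.39 ± 0.20 (other probe 0.74), the activin antagonist FST by 1.26 ± 0.24 and the urokinase PLAU, whose receptor PLAUR of the ERK pathway feedback list rose by 1.11 (other probes 0.30 and 1.07), by 0.94 ± 0.16. The cornified envelope genes SPRR2D and SPRR2F rose by 1.37 ± 0.20 and 1.23 ± 0.19.

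Among the 36 genes that fell with NRG1 in CYT2 cells were FBXO32 (-1.36, other probe -0.60), TXNIP (-0.83), SESN2 (-0.82), PDK4 (-0.81, detected on 3 of 4 arrays with NRG1), PIK3IP1 (-0.77), SESN1 (-0.65) and CDKN1B (-0.64), which textbooks name as targets of FOXO transcription factors. Lower FOXO activity is a candidate explanation, tested on a list of such targets put together after these falls, and after the values of some other members, such as ERBB3, had been seen, so the list is not independent evidence. GADD45A, another textbook target whose value had been seen, was left out of it, and at 0.24 ± 0.15 in CYT2 cells it lay on the other side of 0. Over the 23 other measured members, none past the threshold in CYT2 cells, the median was -0.11 in CYT2 cells (15 below 0, camera p = 0.21 with an estimated correlation), -0.12 in CYT1 cells (19 below 0, p = 0.035) and -0.06 in vector cells (13 below 0, p = 0.50), none of these p adjusted over the 6 tests made. Over all 30 measured members, the 7 that fell included, the median was -0.17 in CYT2 cells (camera in limma, p = 0.033 with an estimated correlation), -0.18 in CYT1 cells (p = 0.017) and -0.04 in vector cells (p = 0.52). The 23 were picked by not passing in CYT2 cells, which takes the clearest CYT2 falls out of that test. So their p-values in CYT2 and CYT1 cells are not on a par. The 30 include the 7 genes that prompted the list, which pulls the other way. The explanation stays open.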
